A study of Sus scrofa with 12 samples.

How the data were processed

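The 12 arrays came from pig skeletal muscle at 4 ages, day 0 (within 24 hours of birth), 7, 14 and 21, with 3 biological replicates per age. Per the labels' protocols, tissue was kept in liquid nitrogen, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of it. The deposited values are linear intensity signals per probe set, made with MAS5 per the submitters' processing notes, which give no version. Every array had the same 2% trimmed mean (500.1, spread 0.00514%), as the global scaling of MAS5 gives. Detection calls were not used here.

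The signals were taken as log2 with no further normalization, since the trimmed means differed by less than the 5% allowed. Of 24123 probe sets, 124 controls were left out, and of the other 23999 the lowest 40% by mean log2 signal were left out (limit at a signal of 90.3), which left 14399. Symbols came from the probe table, with 10099 probe sets carrying 1 symbol, 198 several and 13826 none; 9989 were matched to current names by Entrez identifier, which changed 0 symbols. A gene was represented by its tested probe set with the highest mean signal, which gave 5296 genes, of which 1396 had more than 1 tested probe set. Of the 92 genes with more than 1 probe set called between day 21 and day 0, BUD23 had probe sets called in opposite directions. The always-followed genes MYH1, MYH3, MYH4, MYH8, PAX7 and MYOG carry no symbol in the probe table used here.

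Each probe set was fitted in limma 3.58.1 (R 4.3.3) with a mean for each age over all 12 arrays, and moderated with eBayes with a mean-variance trend. An F test asked for any change with age, and contrasts compared day 21 with day 0, each age with the age a week before, and the first week's change with the third week's. Probe sets passed at a Benjamini-Hochberg adjusted p of 0.05, and counts were also taken at an absolute log2 change of at least 1. The 28 gene lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene where at least 4 members were measured, with an estimated correlation and fry, which asks whether the members changed at all and not against the other genes, as alternatives, and members were also adjusted over the list alone. Day 21 against day 0 and day 7 against day 0 share the day 0 arrays and are not compared with each other. Array measures at day 0 were compared with the 9 later arrays by exact two-sided permutation tests, adjusted over the family of 12.

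The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, among genes past the threshold whose ages do not overlap, the 12 largest rises and 12 largest falls between day 0 and day 21 and the 5 largest of each per week, up to 4 members of each list in order of p, and a set of muscle genes always. The alternatives were no filter, a stricter filter of 60%, quantile normalization, median centring, an offset (the 20th percentile of all signals, 29.7) added before the logarithm, no variance trend, array weights, the replicate number as a block, only the 6 arrays compared, and leaving out each array. Scaling on the 27 hybridization control probe sets and the poly-A spike 3' to 5' ratio as a covariate were chosen after seeing the data.

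The fits were tested on simulated data with the same design, with 100 probe sets changed 2-fold and 100 changed 4-fold among 14399. Of these, 37 and 88 were recovered for day 21 against day 0 with 2 unchanged ones called, 45 and 92 for day 7 against day 0 with 12, 35 and 88 for day 14 against day 7 with 4, 29 and 89 for day 21 against day 14 with 8, and 8 and 62 for the difference between weeks with 3. Camera called 5 of 5 raised lists and 0 of 35 unchanged ones, and with no change added the F test called 0 probe sets. Most 2-fold changes were thus missed with 3 arrays per age. The simulated genes varied independently of each other, so false list calls among genes that move together were not tested. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.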

Results

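Gene expression was measured in skeletal muscle of newborn pigs on Affymetrix porcine arrays. Each transcript is read there by a set of short probes (a probe set) whose brightness follows the amount of labelled RNA. The 12 arrays fell into 4 ages with 3 biological replicates each, namely within 24 hours of birth (day 0) and at days 7, 14 and 21. The sampling asked which genes change over the first 3 weeks of life and in which week. Every array had a trimmed mean signal of 500.1, and the median signal per array lay between 145.4 and 171.7. After removal of dim and control probe sets, 14399 probe sets were tested, of which 7144 carried 1 gene symbol and stood for 5296 genes. The number of arrays limits the precision, and the p-values of single probe sets measure the spread between these samples. Camera p-values at the preset correlation rest mainly on the spread between genes. Changes are log2 differences between the means of 2 ages, given ± SE with n = 3 arrays per age unless stated otherwise. Adjusted p-values come from limma with Benjamini-Hochberg adjustment over all probe sets tested.

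The day 0 arrays stood apart from the other 9 in several measures from the control probe sets. The 3' to 5' log2 ratio of the poly-A spike-in RNAs, a sign of how complete the labelling was, averaged 0.84 ± 0.56 (SD, n = 3) at day 0 and 0.30 ± 0.12 (SD, n = 9) later (exact two-sided permutation p = 0.00455, adjusted 0.0109 over 12 array measures). It reached 1.49 in day 0 replicate 2, and without that array the difference went from 0.54 to 0.22. At the same exact p, the hybridization controls added in fixed amount differed at day 0 by -0.35, the 28S ribosomal RNA probe sets by -1.87 and the 18S probe sets by -1.29. The 3' to 5' ratios of the pig's own actin, GAPDH and EF1A transcripts gave exact permutation p-values of 0.709, 0.364 and 0.623. Pairs of day 0 arrays had a median correlation of 0.918, pairs of the same later age 0.945, pairs of different later ages 0.943, and day 0 paired with a later age 0.888. Day 0 replicate 3 lay nearer to the later arrays, at -35.0 on the first principal component against -62.6 and -62.7 in the other day 0 arrays and 10.8 to 25.2 in the later ones.

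Over the 4 ages, 1278 probe sets (594 genes) changed in the limma F test. The count was 816 without day 0 replicate 1, 566 without day 0 replicate 2, 831 without day 7 replicate 2, and 124 with the poly-A spike ratio as a covariate.

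**Figure D1:**
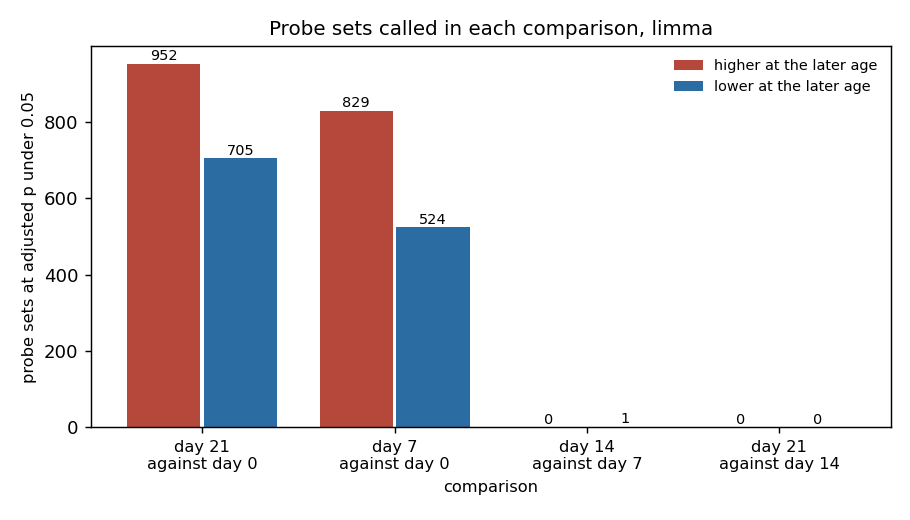
Number of probe sets at adjusted p under 0.05 (vertical axis, from 0) in each comparison of 2 ages (horizontal axis), split into those higher and those lower at the later age. Day 21 against day 0 had 952 higher and 705 lower and day 7 against day 0 had 829 higher and 524 lower, while the second week and the third week had 1 and 0 in total; with arrays scaled on the hybridization controls the first 2 splits were 397 higher with 2486 lower and 358 higher with 1636 lower.

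Between birth and day 21 the largest rises with no offset added were in ANKRD37, an ankyrin repeat protein (5.16 ± 0.65), CYP3A29, a pig cytochrome P450 enzyme (4.53 ± 0.54), and CCNB1, the cyclin that drives entry into mitosis (4.24 ± 0.93). MSTN, the secreted inhibitor of muscle growth myostatin, rose by 3.86 ± 0.62, and GAMT, which makes creatine, by 3.65 ± 0.48. CCL5, a chemokine that attracts white blood cells, rose by 3.33 ± 0.46, SMAGP, a cell adhesion protein, by 3.14 ± 0.39, and GBP1, an interferon-induced GTPase, by 2.96 ± 0.77. GPD1, a glycerol 3-phosphate dehydrogenase, rose by 2.87 ± 0.42 and the ubiquitin-like protein UBD by 2.74 ± 0.39. MYH2, the myosin heavy chain of fast oxidative (IIa) fibres, rose by 2.74 ± 0.28, and the protease inhibitor SLPI by 2.70 ± 0.43. The largest falls were in TNFRSF12A, the TWEAK receptor (-2.73 ± 0.55), NME1, a nucleoside diphosphate kinase (-2.55 ± 0.28), and CDKN3, a phosphatase that acts on cyclin-dependent kinases (-2.50 ± 0.35). MLLT11 (-2.43 ± 0.30), PWP2, a factor of ribosome assembly (-2.31 ± 0.41), and HSPB7, a small heat shock protein of muscle (-2.22 ± 0.31), also fell. RCAN1, an inhibitor of calcineurin (-2.14 ± 0.52), DDAH1, which breaks down methylated arginines (-2.04 ± 0.35), and the imprinted RNA MEG3 (-1.97 ± 0.21) followed. The imprinted PEG10 (-1.94 ± 0.37), CASQ2, a calcium-binding protein of the sarcoplasmic reticulum (-1.90 ± 0.40), and GPATCH4 (-1.90 ± 0.32) completed the 12. By the rule that chose these 24 genes, their 3 values at day 21 lie outside the 3 at day 0. Their limma adjusted p-values ran from 0.000482 (MYH2) to 0.0267 (GBP1). At day 0 the first 4 rising genes and CCL5, SMAGP, GBP1 and UBD were dim, and PWP2 was dim at day 21. With an offset of 29.7 added to every signal ANKRD37 rose by 2.78, CCNB1 by 2.61 and SMAGP by 1.96. The order then turned, with CYP3A29 (3.89), GAMT (3.51), MSTN (3.19) and GPD1 (2.84) above ANKRD37. The call on GBP1 was lost without day 0 replicate 1 (change 2.40, adjusted p = 0.0880) or day 21 replicate 1 (2.15, 0.110), and with array weights. That on RCAN1 was lost without day 0 replicate 1 (-1.47, 0.0541) or 2 (0.0516) and day 21 replicate 1 (0.0714) or 3 (0.0686). With the poly-A spike ratio as a covariate the calls on CCNB1 (3.64 ± 1.11), GBP1 (2.96 ± 0.97) and RCAN1 (-2.18 ± 0.65) were lost, with larger standard errors and, in CCNB1, a smaller change. Over all alternatives the adjusted p of these 3 genes ran from 3.6e-05 to 0.110.

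Among the genes followed for their role in muscle, MYH7, the slow myosin heavy chain, rose by 0.76 ± 0.19 (limma adjusted p = 0.0228), and IGF1 by 1.15 ± 0.24 (0.00902). The fetal growth factor IGF2 fell by 0.69 ± 0.19 (0.0300). The myogenic factors MYF6 (-0.91 ± 0.44, adjusted p = 0.199), MYOD1 (0.41 ± 0.26, 0.329) and MYF5 (-0.54 ± 0.46, 0.492) did not pass the test. The call on MYH7 was lost without day 0 replicate 1 (0.62, adjusted p = 0.0712) or 2 (0.67, 0.0755) and day 21 replicate 2 (0.70, 0.0667) or 3 (0.71, 0.0794). It was also lost with no filter, without a variance trend, with the poly-A covariate (0.64 ± 0.23) and with arrays scaled on the hybridization controls, where its change was 0.38 (0.00278 to 0.176 over all alternatives). The call on IGF2 was lost without day 0 replicate 2 (-0.59, 0.0984) or 3 (-0.60, 0.0652) and without day 21 replicate 1 (-0.65, 0.0965), 2 (-0.71, 0.0595) or 3 (-0.71, 0.0761). It was also lost with no filter, without a variance trend and with the poly-A covariate (-0.55 ± 0.22), over a range of 0.00223 to 0.157, and its change was -1.07 on the hybridization control scale. That on IGF1 was lost with the hybridization controls (0.77) or the covariate (0.81 ± 0.23), over a range of 0.00706 to 0.0757.

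In all, 1657 probe sets differed between day 21 and day 0, 952 higher (390 genes) and 705 lower (376 genes). By at least 2-fold, 584 were higher and 294 lower. The 3 values of one age lay outside those of the other in 29.1% of all probe sets, where chance gives 10%. The signals are scaled to an equal trimmed mean per array. Scaling on the hybridization controls instead shifted the median of all probe sets by -0.36 between day 0 and day 21 and by -0.31 between day 0 and day 7. The split for day 21 became 397 higher and 2486 lower. Changes here are relative to the equal trimmed mean. The count was 843 with the poly-A spike ratio as a covariate, 879 without day 21 replicate 1 and 789 without day 21 replicate 3.

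**Figure D2:**
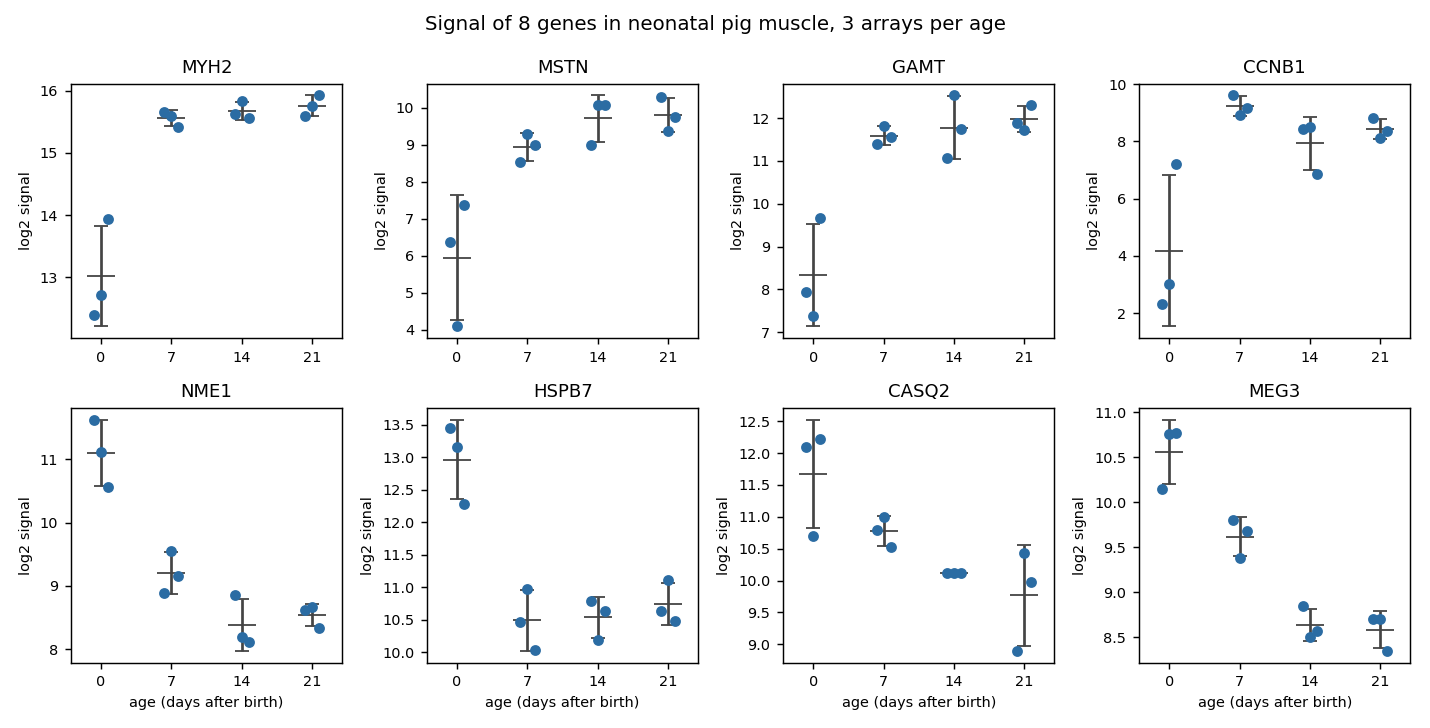
Log2 signal (vertical axes) of 8 genes against age in days (horizontal axes), with a point for each of the 3 arrays per age and a bar for the mean ± SD. From day 0 to day 21 MYH2, MSTN, GAMT and CCNB1 rose by 2.74, 3.86, 3.65 and 4.24, and NME1, HSPB7, CASQ2 and MEG3 changed by -2.55, -2.22, -1.90 and -1.97; each of these kept its sign under every scaling.

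Of the 28 gene lists fixed before the data were examined, 25 had at least 4 measured genes, and 12 shifted against the other genes between day 0 and day 21 (limma camera, preset correlation 0.01), 9 upward and 3 downward. None passed with an estimated correlation, where the lowest adjusted p was 0.346, and fry called 10 of the 12. The spike ratio, hybridization controls and ribosomal RNA signals above moved with day 0 as well. Genes of the proteasome, which degrades ubiquitin-tagged proteins, were lower in 29 of 29 measured members, and 14 fell, or 20 adjusted over the list alone. Examples are PSMD1 (-0.97 ± 0.16), PSMB2 (-1.04 ± 0.18) and PSMA4 (-0.84 ± 0.14). The list had an adjusted p = 0.346 with an estimated correlation. Of 16 genes of glycolysis and glycogen use 11 rose and 0 fell, or 13 and 1 adjusted over the list alone. Among them were PHKB, a subunit of phosphorylase kinase (1.32 ± 0.18), PGAM2, the muscle phosphoglycerate mutase (1.22 ± 0.17), and GPI, glucose phosphate isomerase (2.02 ± 0.31), and the list had an adjusted p = 0.346 with an estimated correlation. In excitation contraction coupling, the calcium release that starts contraction, 5 of 8 genes rose, and 5 adjusted over the list alone. They included CAMK2G (1.89 ± 0.24), CALM2 (1.30 ± 0.17) and CACNA2D1 (1.35 ± 0.26), with a list adjusted p = 0.346 with an estimated correlation. Of the slow fibre isoforms 7 of 9 rose and 1 fell, with the same counts adjusted over the list alone. Day 0 replicate 3 stood at 0.37 in this list against -0.22 and -0.15 in the other day 0 arrays, above day 21 replicate 1 (0.34). The slow troponins TNNT1 (1.37 ± 0.23) and TNNC1 (1.11 ± 0.20) and the slow light chain MYL2 (1.01 ± 0.17) rose and CASQ2 fell. On the hybridization control scale TNNC1 was at 0.73 and MYL2 at 0.63. The list's adjusted p = 0.369 with an estimated correlation. Of the fast fibre isoforms 3 of 8 rose, led by MYH2, or 5 adjusted over the list alone. The median change was 0.38, and -0.00 with arrays scaled on the hybridization controls, and the list's adjusted p = 0.369 with an estimated correlation.

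MHC class I molecules present peptides from inside the cell. Of 24 genes in the list of interferon-induced and MHC class I genes, 24 were higher and 12 rose, or 16 adjusted over the list alone. Examples are SLA-2 (1.34 ± 0.26), SLA-6 (1.68 ± 0.35) and IFI44L (2.12 ± 0.45), with a list adjusted p = 0.346 with an estimated correlation. Of 7 MHC class II genes, which mark antigen-presenting cells, 6 rose and 0 fell, or 6 and 1 adjusted over the list alone. Among them were SLA-DRB1 (2.21 ± 0.21), SLA-DQA1 (1.67 ± 0.23) and SLA-DQB1 (1.97 ± 0.37), and the list had an adjusted p = 0.346 with an estimated correlation. SLA genes are close relatives whose probe sets may read each other's transcripts. Among macrophage markers 2 of 10 rose, or 2 up and 1 down adjusted over the list alone, with LAPTM5 at 1.55 ± 0.32, and the list did not pass (camera adjusted p = 0.292). Among 11 endothelial markers 3 rose and 1 fell, or 5 and 1 adjusted over the list alone. CDH5, the vascular cadherin, was at 1.22 ± 0.23 and ENG at -1.06 ± 0.20, with a list adjusted p = 0.346 with an estimated correlation. Both lymphocyte markers measured were too few for a list test, with CCL5 rising as above and JCHAIN at -0.69 ± 0.47 (limma adjusted p = 0.371). The endothelial call was lost without day 0 replicate 3 (adjusted p = 0.0681) or day 21 replicate 1 (0.0537), within a range of 0.00101 to 0.346. Day 21 replicate 2 stood at 0.12 in this list against 0.66 and 0.57 in the other day 21 arrays. Without it the list median went from 0.51 to 0.81. With the poly-A spike ratio as a covariate SLA-6 (1.39 ± 0.41) and LAPTM5 (1.23 ± 0.36) were no longer called (over all alternatives, 0.00276 to 0.0701).

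Of 25 cell cycle genes 8 rose and 1 fell, or 13 and 1 adjusted over the list alone. The day 0 arrays spread widely in this list. Replicate 3 stood at 0.71 against -0.50 and -0.20 in the others, near day 21 replicate 2 (0.88) and above day 14 replicate 3 (0.23). The rises included NUSAP1 (1.76 ± 0.30) and STMN1 (1.51 ± 0.28), which act on the mitotic spindle, besides CCNB1, and CDKN3 fell. The list's adjusted p = 0.346 with an estimated correlation. Of 10 imprinted growth genes 1 rose and 3 fell, or 1 and 4 adjusted over the list alone. MEG3, PEG10 and IGF2 were the falls, and the list's adjusted p = 0.346 with an estimated correlation. The imprinted call was lost without day 0 replicate 3 (0.169) or day 21 replicate 3 (0.0518), with arrays scaled on the hybridization controls and with the mean of a gene's probe sets (0.00427 to 0.346 over all alternatives). Oxidative phosphorylation had 4 rises and 1 fall among 59 genes, or 3 and 1 adjusted over the list alone. It was led by COX7A1 (0.96 ± 0.18), with a median of 0.16. On the hybridization control scale COX7A1 was at 0.58 and the median became -0.22, and it was 0.07, 0.09 and 0.33 without day 0 replicates 1, 2 and 3. Ribosomal proteins had 0 rises and 2 falls among 57, or 0 and 1 adjusted over the list alone, with RPL3 at -1.26 ± 0.18 and a median of -0.08. This was -0.17, -0.03 and -0.04 without day 0 replicates 1, 2 and 3 and -0.05 without day 21 replicate 1. Both had an adjusted p = 0.869 with an estimated correlation. The first was lost without day 0 replicate 1 (0.460) or 2 (0.369) or day 21 replicate 1 (0.181) or 3 (0.0722). It was also lost with quantile normalization, without a variance trend, on the hybridization control scale, with the covariate, with the mean of a gene's probe sets and in fry, over a range of 6.1e-07 to 0.991. The second was lost without day 0 replicate 2 (0.329) or 3 (0.187) or day 21 replicate 1 (0.306). It was also lost with the stricter filter, without a variance trend, with the covariate and in fry, over a range of 2.4e-12 to 0.869.

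**Figure D3:**
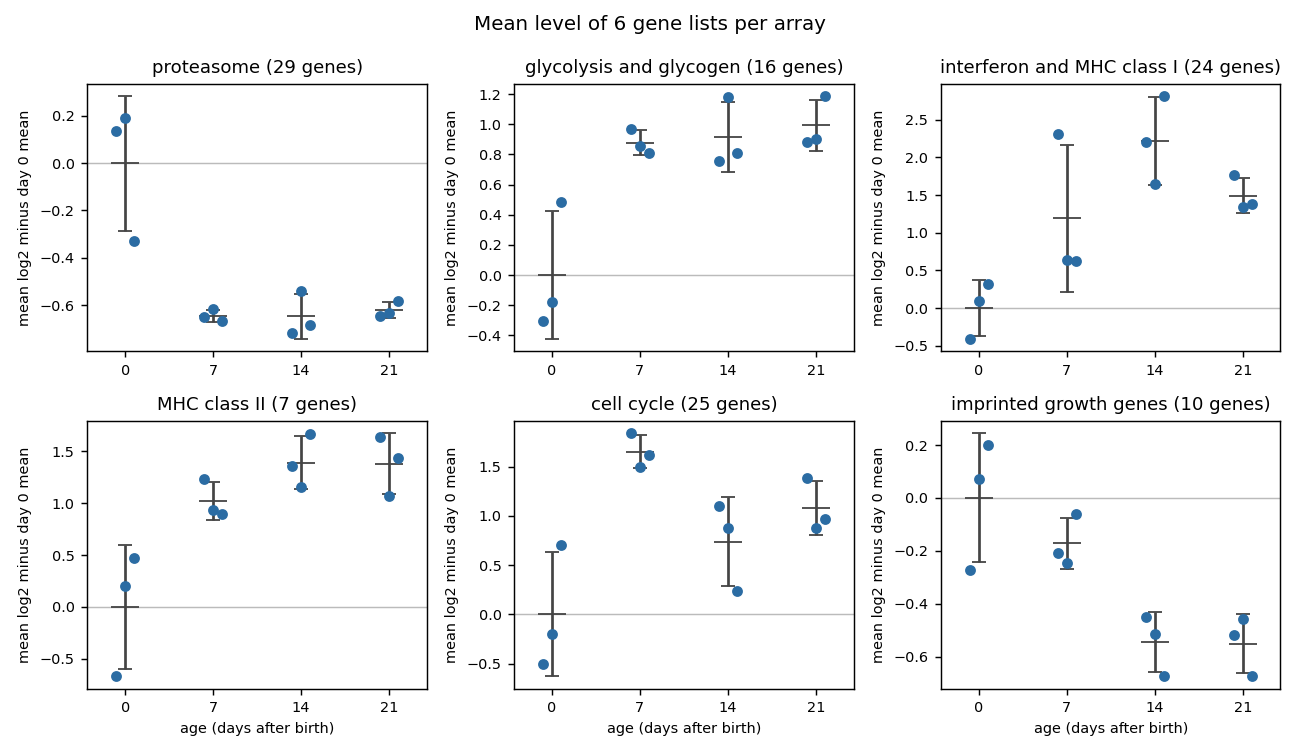
Mean log2 signal of the measured genes of 6 lists in each array, minus the list's day 0 mean (vertical axes), against age in days (horizontal axes), with a point per array and a bar for the mean ± SD of 3 arrays. In the 29 proteasome genes all 9 later arrays lay below the 3 day 0 arrays, and in the 24 interferon and MHC class I genes day 7 replicate 1 stood at 2.31 while the other day 7 arrays stood at 0.64 and 0.62.

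From day 0 to day 7 ANKRD37 rose by 5.38 ± 0.65, CCNB1 by 5.04 ± 0.93, CENPF, a kinetochore protein, by 3.99 ± 0.82, SMAGP by 3.63 ± 0.39 and GAMT by 3.26 ± 0.48. HSPB7 (-2.47 ± 0.31), PWP2 (-2.32 ± 0.41), DDAH1 (-2.27 ± 0.35), MYO5B, a motor protein (-2.25 ± 0.31), and SRM, which makes spermidine (-2.06 ± 0.29), had the largest falls. ANKRD37, CCNB1, CENPF, SMAGP, MSTN and CCL5 were dim at day 0 and PWP2 at day 7. With the offset of 29.7 ANKRD37 rose by 2.97, CCNB1 by 3.35, SMAGP by 2.37 and CCL5 by 1.26. MYH2 rose by 2.54 ± 0.28, MSTN by 2.997 ± 0.62 and IGF1 by 0.90 ± 0.24. MYH7 (0.32 ± 0.19, limma adjusted p = 0.320) and IGF2 (0.07 ± 0.19, 0.870) did not pass. TNNT2, the cardiac troponin T also made in immature muscle, rose by 2.41 ± 0.57 and CCL5 by 2.03 ± 0.46. Adjusted p-values of the genes called here ran from 0.000778 (SMAGP) to 0.0342 (IGF1). Single arrays ended the call on MSTN (day 7 replicate 2, adjusted p = 0.0511) and on CCL5 (day 0 replicate 2, 0.0584, and day 7 replicate 2, 0.0762). They also ended that on TNNT2 (day 0 replicates 1 and 2, 0.0583 and 0.0637, and day 7 replicates 2 and 3, 0.0905 and 0.0543) and on IGF1 (day 0 replicate 2, 0.101, and day 7 replicates 1, 2 and 3, 0.0957, 0.0947 and 0.0858). The call on IGF1 was also lost with no filter and on the hybridization control scale, where its change was 0.59. With the poly-A spike ratio as a covariate the calls on MSTN (1.40 ± 0.48), IGF1 (0.45 ± 0.25), CCNB1 (4.25 ± 1.23), CENPF (3.89 ± 1.13), GAMT (2.52 ± 0.57), DDAH1 (-1.88 ± 0.44), TNNT2 (2.32 ± 0.78) and CCL5 (1.47 ± 0.58) were lost. Over the 1353 probe sets called in this week the covariate left a median share of 0.953 of the change, with standard errors larger by a median factor of 1.31. Over all alternatives the adjusted p of these genes ran from 2.4e-05 to 0.386.

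Of the 25 lists tested, 9 shifted in the first week, 7 upward and 2 downward, none with an estimated correlation (lowest adjusted p = 0.450), and fry called 6. Cell cycle genes were higher in 23 of 25, with 14 rises and 1 fall, or 19 and 1 adjusted over the list alone. Examples are the chromatin protein HMGB2 (1.60 ± 0.18), NUSAP1 (2.44 ± 0.30) and CKS2 (2.04 ± 0.25), against CDKN3 (-1.99 ± 0.35), with a list adjusted p = 0.450 with an estimated correlation. The proteasome was lower in 29 of 29, with 15 falls, or 22 adjusted over the list alone, including PSMD3 (-1.29 ± 0.20) and PSMD1 (-0.83 ± 0.16). Glycolysis had 10 rises among 16, or 11 adjusted over the list alone, including GPI (2.07 ± 0.31), PHKB (1.08 ± 0.18) and PGAM2 (1.004 ± 0.17). Both lists had an adjusted p = 0.450 with an estimated correlation. Excitation contraction coupling had 3 rises among 8 (4 adjusted over the list alone), with CALM2 at 1.19 ± 0.17 and CAMK2G at 1.56 ± 0.24. MHC class II had 4 among 7 (6 up and 1 down adjusted over the list alone), with SLA-DRB1 at 1.75 ± 0.21 and SLA-DQA1 at 1.36 ± 0.23. Day 0 replicate 1 stood at -0.67 in the MHC class II list against 0.20 and 0.47 in the other day 0 arrays. Interferon and MHC class I had 5 rises among 24 (10 adjusted over the list alone), with IFI44L at 1.81 ± 0.45. Day 7 replicate 1 stood apart in this list, at 2.31 above the day 0 mean against 0.64 and 0.62, and without it the list mean went from 1.19 to 0.63 (camera adjusted p = 0.000337, range 1.4e-10 to 0.506). Each of these 3 lists had an adjusted p = 0.506 with an estimated correlation. Endothelial markers had 3 rises and 1 fall among 11 (6 and 1 adjusted over the list alone), with CDH5 at 1.43 ± 0.23 and PECAM1 at 0.88 ± 0.16, or 0.57 on the hybridization control scale (list adjusted p = 0.450 with an estimated correlation). Fast fibre isoforms had 1 rise among 8 (1 adjusted over the list alone), which was MYH2 (0.778 with an estimated correlation). Ribosomal proteins had 2 falls among 57 (1 adjusted over the list alone), with RPL3 at -1.01 ± 0.18 (0.842 with an estimated correlation). IFI44L was not called without day 0 replicate 1 (1.59, limma adjusted p = 0.0737) or day 7 replicate 1 (1.21, 0.0793), nor with array weights. The fast fibre list was not called without day 0 replicate 1 (0.0645), with quantile normalization, in fry or on the hybridization control scale, where its median was -0.05 (list range 0.000230 to 0.778). Fry, which asks whether the members changed at all, did not call the interferon and MHC class I list or the ribosomal proteins. The poly-A covariate ended the calls on the ribosomal protein list and on CDKN3 (-1.67 ± 0.46), PSMD1 (-0.79 ± 0.21), PHKB (0.99 ± 0.24), PGAM2 (0.75 ± 0.20), RPL3 (-0.78 ± 0.23), CDH5 (1.38 ± 0.31) and IFI44L (1.93 ± 0.61) (gene range 5.3e-05 to 0.135).

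In total 1353 probe sets differed between day 7 and day 0, 829 higher and 524 lower, of which 529 and 202 by at least 2-fold. With arrays scaled on the hybridization controls 358 were higher and 1636 lower. The ages did not overlap in 28.5% of probe sets, against 10% by chance. The count was 728 without day 0 replicate 2, 528, 493 and 569 without day 7 replicates 1, 2 and 3, and 229 with the poly-A spike ratio as a covariate.

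Between day 7 and day 14 1 probe set, to which the probe table gives no symbol, fell by 3.16 ± 0.38 (limma adjusted p = 0.0182). Its mean log2 signal was 12.37, 10.81, 7.65 and 6.70 at the 4 ages. As the single call it was picked out after its value was seen. At an unadjusted p under 0.05 there were 857 probe sets, where 720 of 14399 would be expected. In 14.1% the ages did not overlap, against 10% by chance. No member of any list passed over all probe sets, yet 8 lists shifted in camera. Cell cycle genes were lower at day 14 in 25 of 25, with a median of -0.89 and 10 falls adjusted over the list alone. Examples are HMGB2 (-1.09 ± 0.18, adjusted p = 0.219 over all probe sets) and PCNA (-0.89 ± 0.23, 0.620), with a list adjusted p = 0.416 with an estimated correlation. Interferon and MHC class I genes were higher in 23 of 24 with a median of 0.999, for example IFI44L (1.49 ± 0.45) and ISG15 (2.56 ± 0.91). Without day 7 replicate 1, which stood at 2.31 above the day 0 mean against 0.64 and 0.62 in the other day 7 arrays, the list mean went from 1.03 to 1.59. Over the 9 later arrays age gave an exact permutation test p = 0.25 for the list level, a test chosen after the values were seen. The list had 0 adjusted over the list alone and an adjusted p = 0.450 with an estimated correlation. Imprinted growth genes had a median of -0.40, with 1 rise and 4 falls adjusted over the list alone. MEG3 (-0.98 ± 0.21) had the smallest p, and the list an adjusted p = 0.450 with an estimated correlation. The other 5 lists shifted upward with 0 members adjusted over the list alone. They were slow fibre isoforms (median 0.38), fatty acid oxidation (0.18), ubiquitin and autophagy genes (0.28) and the glucocorticoid response (0.26), each with an adjusted p = 0.461 with an estimated correlation, and MHC class II (0.35), with 0.510. Fry called 0 lists. Among the developmental sarcomere isoforms, too few for a list test, the cardiac actin ACTC1, abundant in fetal muscle, was at -1.31 ± 0.22 (limma adjusted p = 0.219). It passed with quantile normalization (0.0396) and on the hybridization control scale (0.00657), over a range of 0.00657 to 0.9997. From day 0 to day 21 it fell by 1.24 ± 0.22 while the embryonic light chain MYL4 rose by 1.17 ± 0.21 and TNNT2 was at 0.76 ± 0.57 (0.417).

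The single call was lost (count 0) without day 0 replicate 2, day 14 replicate 1, 2 or 3 or day 21 replicate 1. The count was 2 without day 7 replicate 1 or 2 and 3 without day 0 replicate 3. Among the lists, the slow fibre isoforms (0.124) and fatty acid oxidation (0.0779) were no longer called without day 14 replicate 1. MHC class II was lost without day 7 replicate 2 (0.0543) or day 14 replicate 3 (0.145) and the glucocorticoid response without day 7 replicate 1 (0.146) or day 14 replicate 3 (0.145). The ubiquitin and autophagy list was lost without day 7 replicate 1 (0.139) or 2 (0.106) or day 14 replicate 3 (0.351). It was also lost with no filter, without a variance trend and with the mean of a gene's probe sets, in all within camera adjusted p-values of 2.0e-05 to 0.510 over the alternatives. Single arrays moved the medians of imprinted growth genes to -0.63 (without day 14 replicate 1), of MHC class II to 0.21 and of ubiquitin and autophagy genes to 0.13 (without day 14 replicate 3) and of the glucocorticoid response to 0.56 (without day 7 replicate 3).

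From day 14 to day 21 limma called 0 probe sets, with 436 at an unadjusted p under 0.05 and 8.44% whose ages did not overlap, against 10% by chance. In camera 7 lists shifted, with 0 members passing over all probe sets or adjusted over the list alone, none with an estimated correlation (lowest adjusted p = 0.4998) and 0 with fry. The 28S ribosomal RNA signal moved in the same week, from a mean of 13.16 at day 7 and 13.05 at day 14 to 12.25 at day 21, where the 3 arrays (12.20 to 12.30) lay below the other later arrays (12.79 or more). Interferon and MHC class I genes were lower at day 21 in 21 of 24 with a median of -0.55, for example MX2 (-1.25 ± 0.37) and IFI44L (-1.18 ± 0.45). Without day 14 replicate 3, which stood at 2.82 above the day 0 mean against 2.20 and 1.65, the list mean went from -0.73 to -0.43 (camera adjusted p = 0.0139, range 4.5e-13 to 0.4998), and the exact permutation test over the later arrays gave p = 0.25 as above. Lower too were the glucocorticoid response (median -0.43, with the glutamine synthetase gene GLUL at -0.55 ± 0.23) and macrophage markers (-0.49, with the mannose receptor MRC1 at -0.60 ± 0.32). So were immediate early and heat shock genes (-0.11, with FOS at -1.87 ± 0.71). Higher were cell cycle (0.31, with CDKN3 at 0.79 ± 0.35), oxidative phosphorylation (0.09) and erythroid genes (0.54, with ALAS2, the first enzyme of red cell haem synthesis, at 0.78 ± 0.27). With an estimated correlation the adjusted p = 0.4998 for interferon, glucocorticoid, macrophage and erythroid genes, 0.726 for immediate early, 0.746 for cell cycle and 0.801 for oxidative phosphorylation. The number of lists called was 11 without day 14 replicate 2, 1 without day 14 replicate 3 and 3 without day 21 replicate 3. Calls were lost without day 14 replicate 3 for the cell cycle (0.460), glucocorticoid (0.225), macrophage (0.235), oxidative phosphorylation (0.235), immediate early (0.0899) and erythroid lists (0.225). They were also lost without day 14 replicate 1 for oxidative phosphorylation (0.210), immediate early (0.0676) and erythroid genes (0.0676). Without day 21 replicate 1 they were lost for cell cycle (0.110), oxidative phosphorylation (0.177), immediate early (0.677) and erythroid genes (0.0861). Without day 21 replicate 3 they were lost for glucocorticoid (0.0716), macrophage (0.235), oxidative phosphorylation (0.110) and erythroid genes (0.110). Quantile normalization ended the call on oxidative phosphorylation and the poly-A covariate that on immediate early genes, within camera adjusted p-values of 2.7e-06 to 0.801 over the alternatives. Without day 14 replicate 3 the medians were 0.13 for cell cycle, -0.16 for glucocorticoid and -0.24 for macrophage genes, and without day 14 replicate 2 they were 0.16 for oxidative phosphorylation, -0.75 for macrophage and -0.04 for immediate early genes. Without day 21 replicate 1 they were 0.18 for cell cycle, 0.05 for oxidative phosphorylation, 0.25 for erythroid, -0.28 for glucocorticoid and 0.05 for immediate early genes. Without day 21 replicate 2 they were 0.16 for oxidative phosphorylation and -0.34 for immediate early genes. Without day 21 replicate 3 they were -0.13 for glucocorticoid, -0.23 for macrophage and -0.31 for immediate early genes.

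Whether the change per week differed was tested on the first week and the third week, which share no array. In 128 probe sets, 90 with the larger value in the first week and 38 with the smaller, the difference passed the test. The split was 39 and 111 with arrays scaled on the hybridization controls. MYH2 moved by 2.54 in the first week and 0.08 in the third week (difference 2.46 ± 0.40, limma adjusted p = 0.0292). ANKRD37 moved by 5.38 and -0.05 (0.0294), SMAGP by 3.63 and -0.02 (0.0206), HSPB7 by -2.47 and 0.21 (0.0292) and MYO5B by -2.25 and 0.72 (0.0198). ANKRD37 and SMAGP were dim at day 0, and with the offset they rose in the first week by 2.97 and 2.37. For MSTN (difference 2.91 ± 0.88, adjusted p = 0.126), CCNB1 (4.55 ± 1.31, 0.114) and IGF1 (0.91 ± 0.34, 0.192) the difference did not pass. The count was 4 with the poly-A spike ratio as a covariate and 12 and 468 without day 0 replicates 2 and 3. It was 15, 3 and 16 without day 7 replicates 1, 2 and 3 and 38, 19 and 3 without day 14 replicates 1, 2 and 3. It was 6, 27 and 31 without day 21 replicates 1, 2 and 3. With the covariate, without day 7 replicate 2 or without day 14 replicate 3, 0 calls had the smaller value in the first week. The calls on HSPB7 and MYO5B were thus lost there. Whether those on MYH2, ANKRD37 and SMAGP held in these settings was not tested.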

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

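The tests of day 0 arrays being made apart, of white blood cells and of single animals were chosen after the result was seen. So were the scaling on hybridization controls, the poly-A spike covariate, the comparison of day 21 with day 7, the probe sets called without the matched arrays and the exchange of later arrays alone. The list tests of the week difference and the tests of array measures were outside the fixed plan. The matched arrays were picked as close in their ratios, which holds for the spike ratio but not for the actin ratio (1.36 against 0.94 and 0.71). The other tests in this part were planned.

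The first week and the third week differed, by a direct test of the difference, in 128 probe sets, and in ANKRD37 (difference 5.43 ± 0.92, limma adjusted p = 0.0294), SMAGP (3.64 ± 0.55, 0.0206), MYH2 (2.46 ± 0.40, 0.0292), MYO5B (-2.97 ± 0.44, 0.0198), HSPB7 (-2.68 ± 0.44, 0.0292), SRM (-2.41 ± 0.42, 0.0294) and DDAH1 (-2.36 ± 0.49, 0.0458). In camera 9 lists differed. They were cell cycle (adjusted p = 1.73e-07), glycolysis (7.16e-06), excitation contraction coupling (0.00855), macrophages (0.00306), MHC class II (0.00164), interferon and MHC class I (7.51e-11) and endothelial cells (0.00269) with the larger value in the first week, and ribosomal proteins (6.68e-05) and the proteasome (2.02e-10) with the smaller. With an estimated correlation none of the 9 passed (lowest adjusted p = 0.474), and fry called 0. Of 100 splits of the arrays drawn, 1, the real one, gave a count as large as 128 (highest other 11), but 0 of the other 99 kept the 3 day 0 arrays together. Of 100 splits that did so and exchanged only the later arrays, 38 gave as many (highest other 813). Where the later ages are alike, any such exchange still sets day 0 against the later arrays, so this outcome was largely fixed by the contrast. The splits thus do not tell a change in the first week from day 0 arrays standing apart. Nor do they show which later arrays carry the count. With the poly-A spike covariate the count was 4. Without single arrays it was 12 and 468 (day 0 replicates 2 and 3), 15, 3 and 16 (day 7 replicates 1, 2 and 3), 38, 19 and 3 (day 14) and 6, 27 and 31 (day 21). With the covariate, without day 7 replicate 2 or without day 14 replicate 3, 0 calls had the smaller value in the first week. The calls on MYO5B, HSPB7, SRM and DDAH1 were thus lost there. Whether those on ANKRD37, SMAGP and MYH2 held in these settings was not tested.

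Signals of control probe sets also differed between day 0 and the 9 later arrays (each exact two-sided permutation p = 0.00455, adjusted 0.0109). The differences were -1.87 in 28S ribosomal RNA, -1.29 in 18S, -0.35 in the hybridization controls and 0.54 in the poly-A spike 3' to 5' ratio. Without day 0 replicate 2 the last of these was 0.22.

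The largest pattern is the difference between day 0 and the later ages. A labelling bias in proportion to the poly-A spike ratio stays open. With that ratio as a covariate 746 of the 1657 probe sets stayed called in the same direction and 911 did not. Within ages the ratio varies mostly through day 0 replicate 2 (1.49 against 0.52 and 0.51 in the other day 0 arrays). The fitted slope thus rests mainly on a single array, and the split was made after the result was seen, so it does not decide. The 911 kept a median share of 0.912 of their change while standard errors grew by a median factor of 1.20. In CCNB1, day 21 against day 0, the covariate gave 3.64 ± 1.11 in place of 4.24 ± 0.93. RNA degradation at day 0 stays open. The pig's own actin, GAPDH and EF1A ratios gave exact permutation p-values of 0.709, 0.364 and 0.623, with 3 arrays at day 0. Day 21 replicate 3 has a spike ratio close to day 0 replicates 1 and 3 and a higher actin ratio (1.36 against 0.94 and 0.71). The spike ratio is a sign of labelling, so pairs matched on it do not test degradation of the tissue RNA. In these pairs probe sets called on the same arrays kept a median share of 1.16 and 0.883 of their change (0.975 over all day 21 arrays without day 0 replicate 2). Probe sets called without the pair kept 0.847 and 0.547. On the hybridization control scale 1102 probe sets stayed called, the 705 falls and 397 (41.7%) of the rises. The rule set before this test was run left scaling undecided at 41.7% of the rises. In a split made after the result was seen, those 397 rises remained on the other scale. For them, scaling of the size these controls show is argued against as the whole cause. It stays open for the other 555 rises, which kept a median share of 0.583. That scale moved the median change by -0.36, which enlarges falls, so the 705 falls do not test scaling. A separate making of the day 0 arrays (exact permutation p = 0.00455 for those controls) cannot be told apart from age, which stays open as an untested biological explanation.

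For the cell cycle list, higher at day 7 than at day 0, signals near background at day 0 stay open. With the offset 15 of the 15 called members were called too. But the offset kept 1345 of all 1353 probe sets called in that week, so this test could hardly have failed. White blood cells in the day 7 samples may contribute. The 19 measured members of the macrophage, lymphocyte and MHC class II lists were higher by a mean of 0.736 ± 0.18 (SE over members). The cell cycle list, with which they share no gene, was higher by 1.65. By list the mean was 1.02 in 7 MHC class II genes, 0.91 in 2 lymphocyte markers and 0.50 in 10 macrophage markers. The macrophage list was not called in that week. The brightest of the 19 at day 7, CD74, was at a mean log2 signal of 9.78 at day 0 and 10.81 at day 7. From day 7 to day 14, when the cell cycle list moved by a mean of -0.92, the same 19 members moved by 0.311 ± 0.08 (SE over members). Without day 14 replicates 3 and 2 they moved by 0.139 and 0.491, where the cell cycle list moved by -0.66 and -0.99. These means give no sign of a loss of these cells. The SE is over genes and not animals, and the macrophage list ran from 0.28 to 1.16 above the day 0 mean over the day 14 arrays. A loss was thus not tested across animals. Proliferation in the muscle itself at day 7 stays open and was not tested.

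The interferon and MHC class I list was highest at day 14. Differences between single animals stay open: the mean square between the 3 later ages was 1.90 times that within ages, with an exact permutation p = 0.25 over 1680 arrangements of the 9 arrays, and single arrays stood at 2.31, 0.64 and 0.62 at day 7. A biological effect of age on this list was not excluded.

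The 4 ages gave 1278 probe sets in the F test, and 1 of 100 splits, the real one, gave as many; the highest other was 1158. All 5 of the other splits that kept the 3 day 0 arrays together had calls, while 44 splits with a pair of them together reached 2 and 50 with each apart reached at most 1. This points to a structure of the samples, day 0 against the rest. For pairs of ages only 10 splits exist, too few for a share under 0.05. As many calls came from 1 of them for day 21 against day 0 (1657, highest other 0), 1 for day 7 against day 0 (1353, highest other 1). They came from 2 for day 14 against day 7 (1, highest other 4), 10 for day 21 against day 14 (0, highest other 0) and 1 for day 21 against day 7 (1, highest other 0). For lists the numbers were 4 (12 lists, highest other 15), 4 (9, 14), 3 (8, 15) and 5 (7, 15) for day 21 against day 0 and the 3 weeks in turn.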

How the results depend on the processing

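The hybridization control scaling, the poly-A spike covariate and the comparison of day 21 with day 7 were chosen after the result was seen, and the other tests here were planned. None of the 101 calls on named genes or 36 calls on lists passed the test in the opposite direction under any alternative run for them. The calls on named genes and lists in the week difference were not among these. On the hybridization control scale the median of oxidative phosphorylation turned (-0.22 for day 21). The median of the fast fibre list also turned on that scale (-0.00 for day 21, -0.05 for day 7). There the splits turned too, to 397 up and 2486 down for day 21, 358 and 1636 for day 7 and 39 and 111 for the week difference. Without day 21 replicate 1 the median of immediate early genes for day 21 against day 14 turned to 0.05. Of 101 calls on named genes 76 held under each alternative run for them and 90 under each planned one, and of 36 calls on lists 19 and 20 did, the estimated correlation and fry not counted; the stricter filter kept 85 of these genes for testing and 35 of these lists, and the fit to only the 6 arrays was run for the counts of probe sets alone. Dim signals limit the arrays: the dimmest 40% of probe sets, below a signal of 90.3, were not tested. Except where stated, the cause was not tested.

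Without the filter the week difference had 76 probe sets. With quantile normalization day 14 against day 7 had 2. Without a variance trend the F test had 818, day 14 against day 7 had 0 and the week difference 12. With array weights the F test had 761 and day 21 against day 7 had 2. On the hybridization control scale the F test had 2105, day 21 against day 0 had 2883, day 14 against day 7 had 2 and day 21 against day 7 had 2. With the poly-A spike covariate the F test had 124, day 21 against day 0 had 843, day 7 against day 0 had 229, day 14 against day 7 had 0 and the week difference 4, with 746 of the 1657 and 209 of the 1353 calls kept in the same direction and standard errors larger by median factors of 1.19 and 1.31. With only the 6 arrays compared, which leaves fewer arrays for the spread, day 21 against day 0 had 590, day 7 against day 0 had 477, day 14 against day 7 had 3 and day 21 against day 7 had 2. With an estimated correlation camera called 0 lists in each of the 4 comparisons, and fry called 0 for day 14 against day 7 and 0 for day 21 against day 14.

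The labels do not say whether equal replicate numbers pair the arrays. Deviations from the age means gave little sign of it, correlating between -0.20 and 0.11 over 18 same-number pairs, 2 of them over 0.1. Of 12 arrays 2 correlated best with their own number, and a weak pairing could be missed. With the number as a block the F test had 899, day 21 against day 0 had 1447, day 7 against day 0 had 1023, day 14 against day 7 had 1, day 21 against day 14 had 0, the week difference 50 and day 21 against day 7 had 2, with 12, 9, 8 and 7 lists, and the call on IGF2 for day 21 was lost (adjusted p = 0.0538, over a range of 0.00223 to 0.157).

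Leaving out 1 array gave an F test between 566 (without day 0 replicate 2) and 1387 (without day 0 replicate 3), day 21 against day 0 between 789 (without day 21 replicate 3) and 2023 (without day 0 replicate 3), day 7 against day 0 between 493 (without day 7 replicate 2) and 1669 (without day 0 replicate 3), day 14 against day 7 between 0 and 3, day 21 against day 14 from 0 to 0 (limma, 436 at an unadjusted p under 0.05 with all arrays), the week difference between 3 and 468, and day 21 against day 7 between 1 and 3. List calls ran from 9 to 13, 8 to 11, 6 to 10 and, for day 21 against day 14, from 1 (without day 14 replicate 3) to 11 (without day 14 replicate 2).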

Other observations

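The 3 added gene lists and the comparison of day 21 with day 7 were chosen after the result was seen, and the other values come from planned tests.

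Falling genes between day 0 and day 21 included genes of protein folding and of ribosome assembly, and 3 lists were then drawn up from what had been seen, so their counts describe these data and test nothing. Of 36 chaperone genes 35 were lower at day 21 and 19 fell. Among them were the mitochondrial chaperones HSPA9 (-0.95 ± 0.13) and HSPD1 (-1.13 ± 0.16) and the endoplasmic reticulum factor MANF (-1.32 ± 0.19), with a list median of -0.75. Of 35 genes of ribosome assembly 31 were lower, 9 fell and 1 rose, with NOP16 (-1.26 ± 0.19) and UTP11 (-1.18 ± 0.21) falling. Of 15 aminoacyl tRNA synthetases, which charge tRNAs, 14 were lower and 9 fell, with EPRS (-1.10 ± 0.19) and FARSA (-1.03 ± 0.18). On the hybridization control scale the medians of the 3 lists were -1.13, -0.94 and -1.32. The ribosomal proteins themselves had 2 falls among 57 and a median of -0.08, and signs of labelling quality moved with day 0 as well.

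Some genes changed between day 0 and day 21 in lists that did not pass. UCP3, a mitochondrial carrier of muscle, rose by 1.73 ± 0.25 and ACADVL, the first enzyme of long-chain fatty acid oxidation, fell by 0.66 ± 0.15 (limma adjusted p = 0.0142, and 0.0531 without day 21 replicate 3, over a range of 0.00174 to 0.0531). On the hybridization control scale ACADVL was at -1.03. ALAS2 rose by 1.40 ± 0.27, COL15A1, a basement membrane collagen, by 1.44 ± 0.27, and IDH3B, a subunit of an enzyme of the citric acid cycle, fell by 0.94 ± 0.19. The acetylcholine receptor subunit CHRNA1 was at -0.79 ± 0.79 (adjusted p = 0.565).

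Between day 7 and day 21 limma called 1 probe set with no symbol, the same as between day 7 and day 14 (-4.11 ± 0.38, adjusted p = 0.000838). There were 959 at an unadjusted p under 0.05 and 16.1% of probe sets whose ages did not overlap, against 10% by chance. The count was 3 without day 0 replicate 3, 2 without day 7 replicate 2 and 2 without day 21 replicate 2.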
